A study of Mus musculus with 2 samples.

How the data were processed

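H3K4me1 ChIP-seq was measured in kidney from pooled mouse embryos of both sexes at day 14.5 after fertilisation, in 2 biological replicates of 1 group, per the labels. Each replicate joins 2 technical replicates, and the labels give a library size range of 300 to 500 bp. Per the labels the strain is B6NTac;B6NCrl/Lap and the control was a separate experiment, represented by 2 control files. The samples differ only by replicate number, so no groups were compared, and every sample was used.

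The authors deposited narrowPeak lists in mm10 coordinates, per the file headers and accompanying notes: a list called on each replicate, a list called on the pooled replicates and a replicated list, which the notes give as derived from the other 3 lists. As 213 of its peaks overlap neither replicate's list, how those lists were used is not known here. The aligner and peak caller are not given in the sources used here, nor is the rule of the replication filter. The fold enrichment of each peak over the control is a ratio that the authors deposited. The significance of each peak was deposited as −log10 of its p-value and −log10 of its q-value. The display score of each peak, from the authors, was read and used for no result. The lowest deposited −log10 p was close to 2 in each list, 2.03 in replicate 1 and 2.02 in replicate 2, and peaks with q-values above 0.05 made up 16.2% and 6.00% of these lists. The lists therefore hold weak peaks, and measures that count every peak depend on that threshold. No read counts are in the files, so the depth is unknown. The 2 lists were compared by overlap, and the fold enrichment of matched peaks was compared without correction for depth. How much sequence a replicate's list covers moves with its depth and with its enrichment over the control, which the lists do not separate.

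The reference was GRCm38, the assembly that mm10 names, with GENCODE vM21 genes. Peak coordinates lay within its chromosome lengths. Coordinates are printed from 1, as in a genome browser. Peaks lay on 19 autosomes and the X chromosome, and none lay on the Y chromosome. Overlapping peak intervals were merged before base pairs were counted. Random placements put each peak at a random position of its own chromosome outside assembly gaps, 100 times with a fixed seed.

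The overlap of the replicates was the share of one list's peaks with at least 1 bp in the other list. For fold enrichment, each replicated peak was matched to the strongest overlapping peak of each replicate. Covered base pairs were assigned to promoters (1000 bp on each side of a TSS), then exons, introns and intergenic sequence. TSS profiles used 21728 protein-coding genes, 1 TSS per gene at its annotated start, split into CpG-rich promoters (observed over expected CpG of at least 0.6 and GC fraction of at least 0.5 within 500 bp) and CpG-poor ones. The measure for genes was the share of the 50 kb on each side of the TSS covered by peaks, in windows of the same width for every gene. A nearby peak need not act on the gene whose window holds it. For each of 19 gene lists the median share was ranked among 10000 random lists of the same size, each member drawn from genes with a similar number of protein-coding TSSs in the window, and medians within the highest or lowest 2.5% were called apart. One hepatocyte symbol, Tf, had no match in the annotation, so 15 of the 16 genes were measured. Domains joined peaks at most 3000 bp apart. Motif densities used windows of 500 bp on each side of summits more than 2000 bp from a TSS, among the 20000 distal peaks of highest fold enrichment. They were divided by densities in flanks 3000 bp away without pooled peaks and set beside 50 letter permutations of each motif. Windows had a GC content of 48.9% and flanks of 45.9%, which the permutations are meant to offset. For GATA 29 permutations exist.

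The gene lists, thresholds, windows, main measures and most alternatives were chosen before the data were examined. The rule for named genes was fixed then too. It takes the 4 members with the largest share and all members without a replicated peak from each kidney list, the 2 largest and the 1 smallest from each other list, the 10 protein-coding genes with the largest share, the genes in the 10 longest domains and those nearest to the 10 peaks of highest fold enrichment. Alternatives varied the peak list, the thresholds on fold enrichment and −log10 q, the overlap rule, windows, matching, annotation, joining distance and motif settings, and used each replicate's own list alone. With 2 replicates, ± gives the SD of their 2 values, and no p-values were computed.

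The functions were tested on simulated data. Coverage matched a base by base count in 500 of 500 windows. Peaks placed at random gave enrichments from 0.990 to 1.03 over the 4 sequence classes. Of 100 random gene lists, each ranked with the 21728 protein-coding genes as background, 1 was in the top 2.5% and 3 in the lowest 2.5%. When the shares of the 15 listed genes were doubled and raised by 1 percentage point, 44 of 100 lists passed, so lists of this size can miss such a difference. An E-box planted in 4000 simulated sequences exceeded all 50 permutations. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.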

Results

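Genome-wide maps of H3K4me1, the monomethylation of lysine 4 on histone H3 that marks enhancers and the flanks of active promoters, were made by ChIP-seq from embryonic mouse kidney. The tissue came from pooled embryos of both sexes at day 14.5. At this age the kidney holds nephron progenitors, a branching ureteric bud, forming nephrons and stroma. The series had 1 group with 2 biological replicates, each made of 2 technical replicates. Without a second group, no test between conditions was possible, and the comparisons are between genes, regions and the 2 replicates. The files hold peaks and no read counts, so the depth of each library is unknown. Peaks had been called by the authors on each replicate and on the pooled replicates. A replicated list, the pooled peaks that passed the authors' replication filter, is used below unless another list is named. It held 84399 peaks covering 52.5 Mb, or 2.05% of the genome, with a median width of 479 bp. The list of replicate 1 held 127722 peaks covering 47.5 Mb, and that of replicate 2 held 156830 peaks covering 67.7 Mb. Fold enrichment over the control is the authors' own value for each peak, and its median was 3.197 in replicate 1, 3.48 in replicate 2 and 3.40 in the replicated list.

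The broadest marking lay over anterior Hox genes, Gse1 and Ncor2. The protein-coding gene with the largest peak-covered share of the 50 kb on each side of its TSS was Hoxb5, a homeodomain factor of body axis patterning, at 62.0%. Its replicate values were 48.2% and 66.0%, a mean of 57.1% ± 12.5 (SD, n = 2). The genome-wide median gene had a share of 2.04%, and 23.8% of 21728 protein-coding genes had a share of 0. Of the 10 genes with the largest shares, 9 were Hox genes, and their windows overlapped within each cluster. On chromosome 11, Hoxb4 had a share of 54.3%, Hoxb6 54.3%, Hoxb3 53.8% and Hoxb7 49.7%. On chromosome 15 Hoxc4 reached 52.9%. On chromosome 6 Hoxa5 reached 50.2%, Hoxa6 49.8% and Hoxa3 46.1%. The exception was Bahcc1 on chromosome 11 (120232947 to 120292296), which encodes a chromatin protein, at 48.3%, with a replicate mean of 45.1% ± 5.85 (SD, n = 2).

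**Figure D1:**
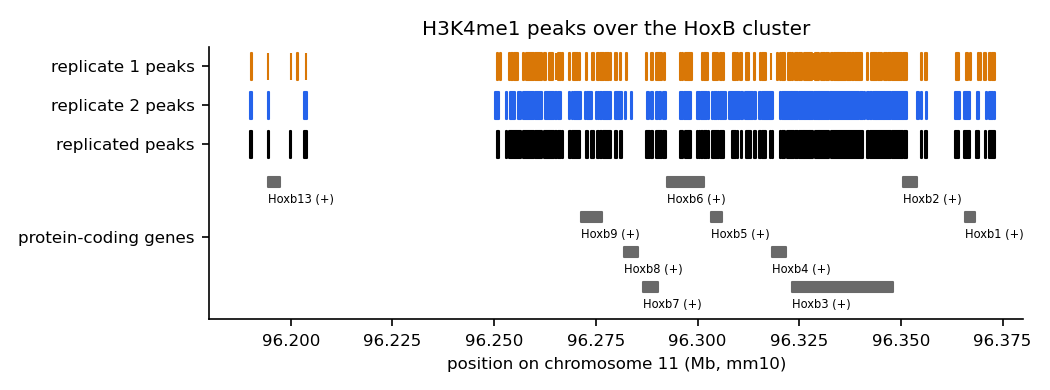
Map of peaks over the HoxB cluster on chromosome 11 of mm10, with position in Mb on the horizontal axis. Each bar is a peak of replicate 1, replicate 2 or the replicated list, grey bars are protein-coding genes with their strand, and the domain from 96295596 to 96351503 spans Hoxb6 to Hoxb2.

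Peaks no more than 3000 bp apart were joined into domains. At this joining distance the longest spanned 84.9 kb inside Gse1 on chromosome 8 (120481242 to 120566107), and 71.7% of it lay under 41 peaks. Another Gse1 domain of 59.3 kb lay further upstream on the same chromosome (120251039 to 120310304). Both also fell within Gm20388, an annotated gene model that spans Gse1. Ncor2, which encodes a nuclear receptor corepressor, held the next domain, of 66.1 kb on chromosome 5 (125119703 to 125185780). The HoxC domain of 59.7 kb on chromosome 15 (102983210 to 103042860) overlapped Hoxc9, Hoxc8, Hoxc6, Hoxc5 and Hoxc4. The HoxB domain of 55.9 kb overlapped Hoxb6, Hoxb5, Hoxb4, Hoxb3 and Hoxb2. The HoxA domain of 52.5 kb on chromosome 6 (52157687 to 52210171) overlapped Hoxa1 to Hoxa6 and the gene models Gm28308 and 5730596B20Rik. Ssbp3, which encodes a single-stranded DNA-binding protein, held 56.0 kb on chromosome 4, and the receptor gene Notch2 held 50.2 kb on chromosome 3. The last of the 10 were Msi2 on chromosome 11, an RNA-binding protein gene, with 50.03 kb, and Ski on chromosome 4, a repressor of TGF-beta signalling, with 49.1 kb. Coverage of the HoxC domain was 45.1% in replicate 1 and 72.1% in replicate 2, the widest gap between replicates among these domains. In all, 151 of 43073 domains reached 20 kb and held 5.03% of the covered base pairs. That count depended on the joining distance and was 15 at 1000 bp and 2985 at the widest distance tried. It also depended on the peak list, with 295 in the pooled list, 205 in replicate 1 and 360 in replicate 2. With −log10 q of at least 5 it was 22, and with fold enrichment of at least 5 it was 4.

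Genes that mark ureteric bud and stroma of the developing kidney lay in more heavily marked surroundings than random genes, and for tubule and podocyte genes this depended on the settings. Of 5 kidney lists, 4 had a median covered share within the top 2.5% of 10000 random gene lists matched on gene density. The ureteric bud and collecting duct list had a median share of 6.01%, against 1.21% for random lists, at percentile 100. The renal stroma list had 5.81% against 1.46%, at percentile 99.9. The podocyte list had 4.16% against 1.499%, at percentile 98.2, and the list for the differentiating nephron tubule 3.83% against 1.51%, also at percentile 98.2. The nephron progenitor list had 3.14% against 1.41% and stayed below the threshold, at percentile 93.7. None of the 14 other lists reached it. Genes are not replicates, so the percentiles describe these libraries and carry no p-value.

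In the nephron progenitor list, 13 of 15 genes had a peak in the window. Hoxd11, a patterning factor needed for kidney development, had a covered share of 24.1% (replicate mean 21.3% ± 5.83 (SD, n = 2)). Its paralog Hoxa11 had 22.4% (20.4% ± 5.36), Meox1, a mesenchymal homeobox gene, 20.3% (19.1% ± 6.65), and Pax2, a regulator of renal lineages, 15.3% (15.7% ± 5.54). The window of Hoxa11 reaches into the HoxA domain over Hoxa5 and Hoxa6. Within 2.5 kb of the Hoxa11 TSS the share was 3.82%, with 6.30% in replicate 1 and 0 in replicate 2. For Hoxd11 the share within 2.5 kb was 18.2%. Eya1 had no replicated peak, though peaks covered 0.920% of its window in replicate 1 and 0.947% in replicate 2. Cited1 had none in either replicate and is on the X chromosome, where coverage was low throughout.

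In the ureteric bud list, 16 of 17 genes had a peak. Wnt11, a ligand expressed at ureteric bud tips, had a share of 15.1% (16.6% ± 4.47). Etv4, an ETS factor downstream of Ret signalling, had 10.7% (11.7% ± 3.004), Wnt7b 9.93% (9.96% ± 3.79) and Cdh16, a kidney cadherin gene, 8.64% (6.69% ± 1.59). Calb1, which encodes calbindin, had none in either replicate. In the tubule list, 16 of 17 genes had a peak. Wnt4, the inducer of nephron epithelium, had a share of 14.2% (14.3% ± 2.09), Pax8 12.7% (11.9% ± 3.01), Hnf1a, a proximal tubule factor gene, 12.3% (12.2% ± 1.02) and the Notch ligand gene Jag1 10.8% (12.3% ± 3.30). Umod, the uromodulin gene of the later thick ascending limb, had no replicated peak.

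All 14 podocyte genes had a peak. Lmx1b, a podocyte transcription factor gene, had a share of 17.6% (16.2% ± 3.09), Vegfa 15.5% (13.6% ± 3.45), Synpo, which encodes synaptopodin, 14.6% (15.03% ± 6.45) and Wt1 12.8% (12.3% ± 3.04). In the stroma list, 15 of 16 genes had a peak. Pbx1, a TALE homeodomain factor gene, had the largest share of any kidney list member, 28.2% (25.8% ± 7.91). Hic1 had 22.1% (21.8% ± 6.13), Pdgfrb, a receptor of pericytes and mesenchyme, 15.3% (14.7% ± 4.09) and Col1a1 9.66% (9.63% ± 3.16), while Penk had no replicated peak.

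By replicate, the ureteric bud, stroma and podocyte lists were past the threshold in each, and the tubule list was at percentile 92.3 in replicate 1 and 98.7 in replicate 2. The number of kidney lists past the threshold fell from 4 to 2 with unmatched random lists, with lists matched on gene length, or with peaks of −log10 q of at least 5, and each time the tubule and podocyte lists were lost. The ureteric bud and stroma lists stayed past it in all 12 alternatives, the tubule list in 7, the podocyte list in 6 and the nephron progenitor list reached it in 2.

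Markers of other cells that a dissected kidney can hold were not set apart. The endothelial list was at percentile 83.6, with Egfl7 at 14.8% and Plvap at 14.7%, and Emcn lowest at 0.563%. The leukocyte and macrophage list was at percentile 67.5, where Lyl1 had 28.4%, Cd68 12.6% and Ptprc 0. The erythroid list was at percentile 46.9, where Nfe2 had 20.8%, Epor 10.1% and Rhag 0, and 2 of its 12 genes were X-linked. The adrenal and gonad list was at percentile 70.8, with Inha at 12.03%, Amh at 11.7% and Cyp11b1 at 0. The sympathetic neuron and chromaffin list was at percentile 79.3, with Gata2 at 9.84%, Chga at 6.57% and Phox2b at 0.475%.

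Among lists for other organs, the epidermis was the lowest, with a median share of 0 against 2.10% for random lists, at percentile 0.395. Sfn had 7.61% and Krt15 6.97%, and Trp63, the master regulator gene of stratified epithelium, had no replicated peak. That list was at percentile 2.09 in replicate 1 and 4.09 in replicate 2, and it stayed in the lowest 2.5% in 6 of 12 alternatives, which ranged from percentile 0.160 to 18.7. The germ cell list was at percentile 12.5, where Prm1 had 9.30%, Tdrd1 5.67% and the X-linked Tex11 0. The hepatocyte list was at percentile 22.5, with Apoh at 7.97%, Foxa3 at 7.90% and Serpind1 at 0. The neuron list was at percentile 51.1, where Neurod2 had 10.98%, Slc17a7 10.7% and the X-linked Syn1 0. The cardiac and skeletal muscle list was at percentile 62.5, with Myh6 at 8.37%, Tnnt2 at 8.06% and Ttn at 0. The lung and gut list was at percentile 64.9, with Sftpc at 10.3%, Scgb1a1 at 4.31% and Foxa2 at 0.476%. The eye list was at percentile 86.5, where Gnat1 had 32.7%, Rho 9.84% and Rcvrn 0. The neural progenitor list was at percentile 90.1, with Hes5 at 7.67%, Neurog1 at 5.28% and Otx2 at 0.224%. The housekeeping list was at percentile 88.4, where Polr2a had 14.3%, Eef2 12.4% and the X-linked Hprt 0. With windows of 10 kb on each side of the TSS, the neural progenitor and housekeeping lists reached percentiles 99.4 and 99.1. With gene bodies the neural progenitor list reached percentile 99.87.

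**Figure D2:**
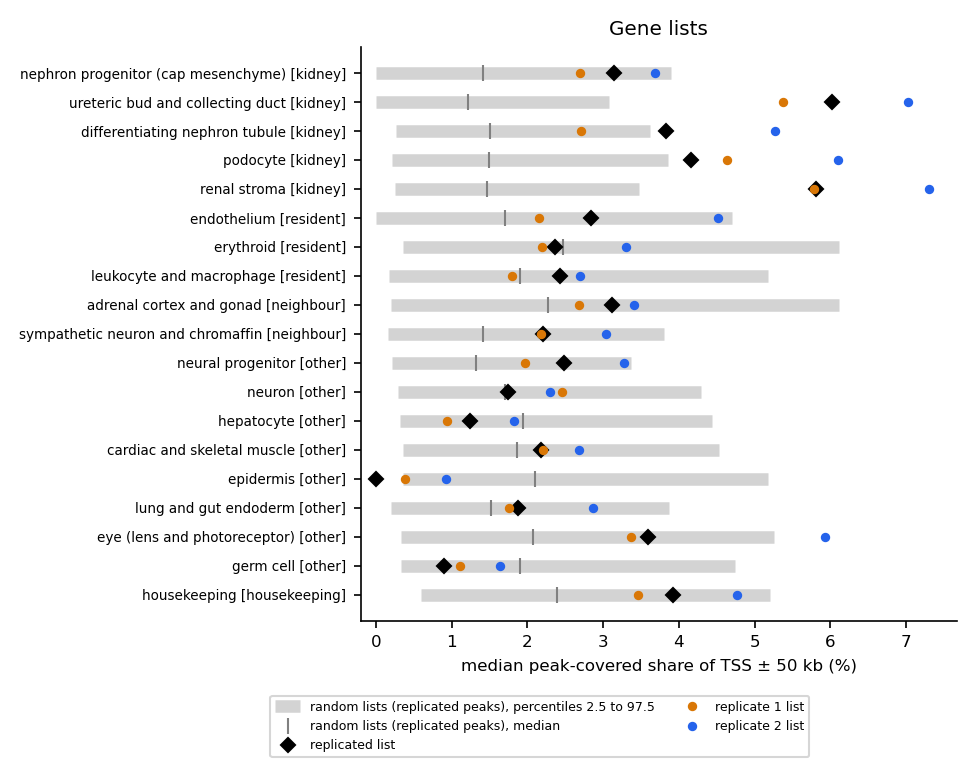
Median peak-covered share of the 50 kb on each side of the TSS, in percent, for 19 gene lists with their class in brackets. Black diamonds are the replicated list, orange and blue points the lists of replicates 1 and 2, and grey bars the range of 10000 random lists without their lowest and highest 2.5%, measured on replicated peaks. The diamonds of 4 kidney lists lie to the right of their grey bars, and the epidermis diamond at 0 lies to the left.

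Promoters in CpG-rich sequence carried the mark on their flanks and not at the TSS itself. Of 9722 CpG-rich TSSs, 44.1% were covered in the bin 1100 to 1200 bp downstream and 23.4% in the bin 900 to 800 bp upstream. At the TSS 5.75% were covered, as the mean of the bins on either side. The replicate means were 43.5% ± 9.79 downstream and 6.27% ± 1.05 at the TSS (SD, n = 2), so the dip exceeded the spread between replicates. A peak lay within 5 kb of 86.4% of these TSSs. Of 12006 CpG-poor TSSs, 36.7% had one within 5 kb, and coverage was 10.1% at the TSS and at most 11.8% downstream. The downstream maximum was 7.66 times the value at the TSS for CpG-rich promoters and 1.17 times for CpG-poor ones. The ratio for CpG-rich promoters rose to 15.6 with peaks of −log10 q of at least 5 and to 43.9 with those of fold enrichment of at least 5.

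**Figure D3:**
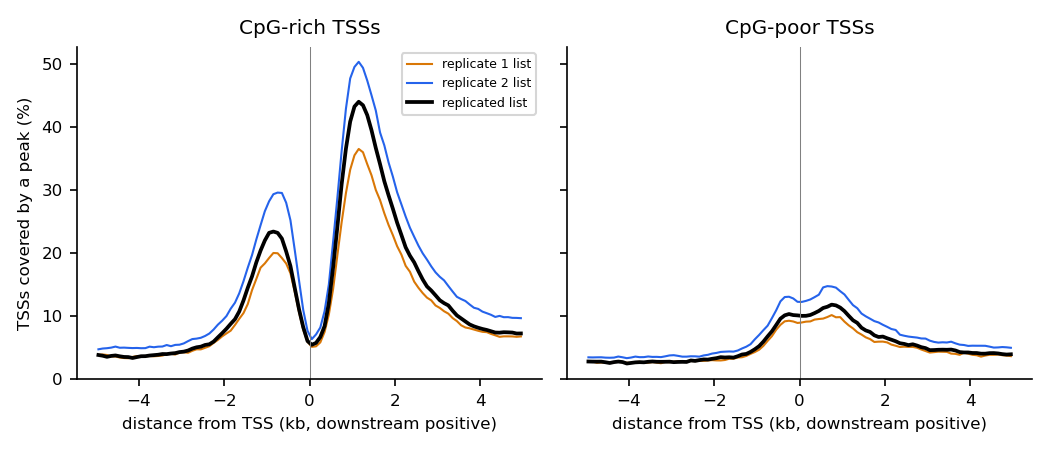
Share of protein-coding TSSs covered by a peak, in percent, in bins of 100 bp from 5 kb upstream to 5 kb downstream, for CpG-rich TSSs on the left and CpG-poor TSSs on the right. The black line is the replicated list and the orange and blue lines are replicates 1 and 2. On the left the black line falls to 5.45% just downstream of the TSS, between maxima of 23.4% and 44.1%.

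Introns held the largest part of the marked sequence, 56.6% of the covered base pairs, 1.37 times the share after random placement on the same chromosome. Promoters, within 1000 bp of a TSS, held 15.6%, an enrichment of 3.42 times. Exons held 4.47%, or 1.41 times, and intergenic sequence 23.3%, or 0.457 times. The replicate lists gave promoter enrichments of 3.16 ± 0.0637 and intergenic values of 0.489 ± 0.00451 (SD, n = 2). Of the summits, 72.7% were more than 2 kb from any TSS and 46.6% more than 10 kb. With protein-coding genes alone as the annotation, promoter enrichment was 5.27.

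The summits of the 10 peaks of highest fold enrichment were all intronic. The first, at fold enrichment 9.92, was a peak of 12661 bp in Cxxc5, a CXXC zinc finger gene, on chromosome 18 (35833838 to 35846498). The strongest peak overlapping it had 9.33 in replicate 1 and 8.88 in replicate 2. The second, at 9.49, lay in Rai1 on chromosome 11 (60176995 to 60179178), 44.7 kb from the TSS of Srebf1, a lipid synthesis regulator gene. Ski held peaks at 9.43 and 8.91 on chromosome 4, and Hspg2, the perlecan gene of basement membranes, held peaks at 8.87 and 8.82 on the same chromosome. Fam129b on chromosome 2 had a peak at 9.05, with 5.02 in replicate 1 and 10.7 in replicate 2. Zmiz1 on chromosome 14 had one at 8.67. The remaining peaks lay in Cacna1g on chromosome 11, nearest to the TSS of Abcc3, at 8.62, and in Sufu on chromosome 19, nearest to that of Trim8, at 8.59.

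The X chromosome was nearly without peaks. Peaks covered 0.0731% of it and 2.19% of the autosomes, a ratio of 0.0335, and 256 of the 84399 peaks were X-linked. Replicate 1 gave a ratio of 0.0400 and replicate 2 a ratio of 0.0537, with a mean of 0.0469 ± 0.00968 (SD, n = 2). A peak lay within 5 kb of 34 of 226 CpG-rich X-linked TSSs, or 15.04% (95% Wilson interval 10.97 to 20.3%). The autosomal share was 88.1% of 9496 (87.4 to 88.7%). In replicate 2 alone the X-linked share was 41.2% (34.9 to 47.7%) and in replicate 1 it was 21.7% (16.8 to 27.5%). These intervals cover counting error only. Of 948 X-linked protein-coding genes, 84.0% had no peak within 50 kb, against 21.1% of autosomal genes. Among autosomes, chromosome 11 was covered most, at 3.83%, and chromosome 3 least, at 1.42%. With peaks of fold enrichment of at least 5, none was on the X chromosome, and with −log10 q of at least 5 the ratio was 0.00843.

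**Figure D4:**
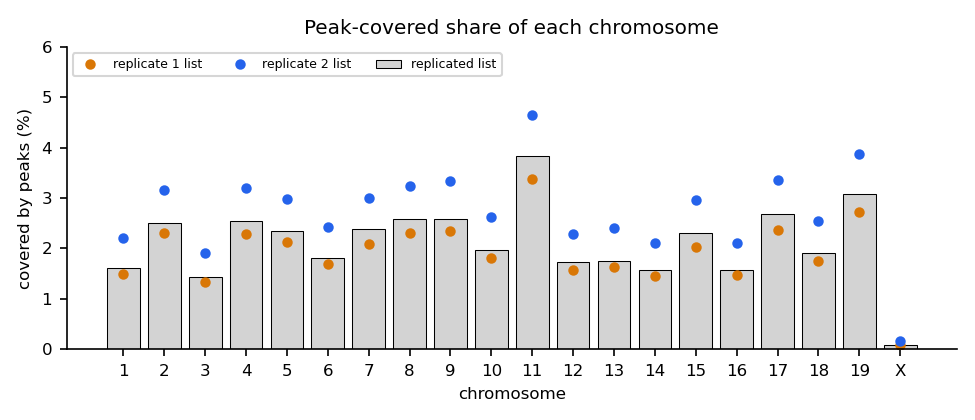
Share of each chromosome covered by peaks, in percent of its sequence, with bars for the replicated list and orange and blue points for replicates 1 and 2. The X chromosome is at 0.0731% in the replicated list, and the autosomes lie between 1.42% and 3.83%.

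The replicates shared the gene neighbourhoods that were marked, and differed in many individual peaks. Across 21728 genes, the covered shares of the 2 replicates had Spearman's rho of 0.969, where genes are not independent replicates. Of replicate 1's peaks, 65.2% overlapped a peak of replicate 2 by at least 1 bp (95% Clopper-Pearson interval 65.0 to 65.5%). After random placement the share was 4.96% ± 0.0588 (SD of 100 placements). Of replicate 2's peaks, 49.6% overlapped one of replicate 1 (49.3 to 49.8%), against 3.99% ± 0.0492. Both intervals treat peaks as independent and cover counting error only. The overlap covered 27.6 Mb, a Jaccard index of 31.6% of all base pairs in either list. The share of peaks that overlapped the other replicate's full list rose with strength. It went from 51.6% to 89.0% between the lowest and highest quintile of replicate 1's peaks by fold enrichment. For replicate 2 it went from 30.7% to 81.6%. A required overlap of 50% of both peaks lowered the shares of all peaks to 29.1% and 23.7%. Between the top 20000 peaks of each list by p-value, the shares were 49.7% for replicate 1 and 44.5% for replicate 2. Limiting both lists to fold enrichment of at least 5 left 3721 peaks of replicate 1, of which 60.8% overlapped, and 12431 of replicate 2, with 17.9%. With −log10 q of at least 5, 71.2% of 7454 and 20.4% of 25610 did. With lists of such unequal length, the share of the longer list is held down by the length of the shorter one.

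**Figure D5:**
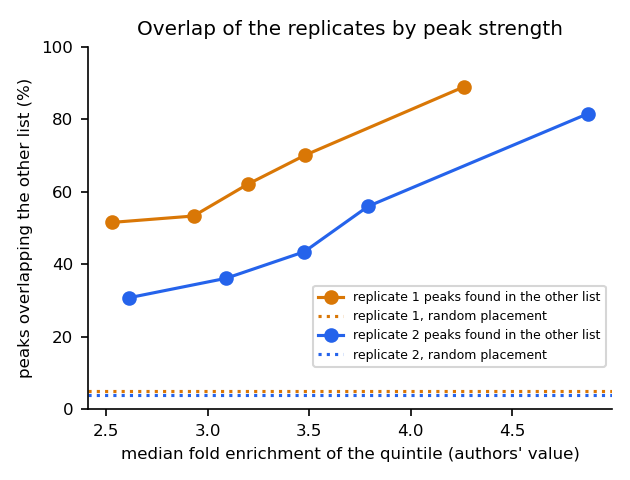
Share of each replicate's peaks that overlap the other replicate's list by at least 1 bp, in percent, against the median fold enrichment of each quintile of the peaks. Solid lines are replicate 1 in orange and replicate 2 in blue, dotted lines are the means of 100 random placements, and the highest quintiles reach 89.0% and 81.6%.

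Among called peaks, fold enrichment itself was weakly related between the replicates. These peaks had passed a calling threshold, and the replicated list had quartiles of 2.96 and 3.90. So narrow a range can lower a correlation. Over 68230 replicated peaks found in both lists, Spearman's rho was 0.350 and Pearson's r of log2 values 0.387, where peaks are not independent. The log2 fold enrichment of replicate 2 was on average 0.20 above that of replicate 1, with an SD across peaks of 0.38. With −log10 q of at least 5, rho was 0.0668. The authors' replication filter kept 64.8% of the 130174 pooled peaks, holding 80.8% of their base pairs. Kept peaks had a median fold enrichment of 3.40 and dropped peaks 2.72. Of the kept peaks, 68230 overlapped both replicate lists, 11545 only that of replicate 2, 4411 only that of replicate 1 and 213 neither. Of the 84399 kept peaks, 5.39% had a q-value above 0.05.

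Consensus motifs of kidney and general factors were counted around distal summits. The density of the E-box CAGCTG in 16844 windows over that in 26140 flanks was a ratio of 1.58. The median for 50 letter permutations of the motif was 1.24. The TEAD motif GGAATG had a ratio of 1.17 against 1.00. The HOX11 motif GTCGTAAA had a ratio of 1.70 against 0.897, from 67 sites in the windows and 61 in the flanks. The GATA motif AGATAA was less dense in the windows than in the flanks, at a ratio of 0.954, but its permutations were lower still, at 0.855. These 4 of the 16 motifs exceeded every permutation. The PAX2/8 motif, at 1.64 against 1.32, was exceeded by 1 of 50 permutations and the HNF4 motif, at 1.01 against 0.999, by 23. The HNF1 motif, which reads the same on both strands, had 2 matches in the windows with both strands counted, too few to compare. Of these 4, only TEAD exceeded every permutation in all alternatives. With the top 5000 distal peaks, 3 of 50 permutations were as high for the E-box and 8 for HOX11. With replicate 1's list alone HOX11 had a ratio of 1.30, with 4 of 50 permutations as high, and with flanks 10 kb away 2 were. For GATA, 2 of 29 were as high with those flanks and 1 with windows of 250 bp on each side of the summit.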

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

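No paired analysis was possible because the series has 1 group. The alternatives with autosomal genes or autosomes alone, matching on density and CpG class, motif permutations keeping CpG and motif counts without each replicate were chosen after seeing the data. Over 173 alternatives for values that answer a comparison, none reversed a direction. Only enrichments, the TSS and X chromosome ratios and list percentiles have a direction that could reverse, while overlap shares, rho, counts and spans do not. The TSS ratios use the maximum over downstream bins, with the bin at the TSS among them, so they could hardly fall below 1. In 92 the call or value held. A value held when it moved by no more than the spread between replicates or its confidence interval. For the overlap shares that spread was the SD of the shares in the 2 directions. These differ with the lengths of the lists too, so this limit is wide. For a count the limit was 50% of the smaller number. Another 68 moved beyond these limits, 11 lost a call and 2 gained one. The ureteric bud list lay between percentiles 98.4 and 100 and the stroma list between 98.97 and 100 in all 12 alternatives that gave a value. With fold enrichment of at least 5 the gene list medians and those of most random lists were 0, so the lists were not ranked there, and with −log10 q of at least 5 the same held for 7 of the 19 lists. Depth is unknown, so its part in the difference between replicates cannot be given. Where no cause is named, the cause was not tested.

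The percentile of the nephron progenitor list rose to 99.7 with windows of 10 kb and to 99.9 with gene bodies, and fell to 83.6 with windows of 100 kb, 87.02 by number of peaks, 80.6 without matching and 76.2 with matching on length. That of the tubule list was 95.9 with −log10 q of at least 5, 91.2 without matching, 91.5 with matching on length, 97.3 with autosomal genes alone, and 92.3 to 98.7 with 1 replicate left out. That of the podocyte list was 84.0 with −log10 q of at least 5, 95.2 with windows of 10 kb, 97.3 with gene bodies, 92.2 without matching, 95.8 with matching on length and 96.6 with matching on density and CpG class. The count of kidney lists set apart was 2 with −log10 q of at least 5, 2 without matching and 2 with matching on length, and 3 with autosomal genes alone, with matching on density and CpG class or with replicate 2 left out. Outside the kidney class it was 2 with windows of 10 kb and 1 with gene bodies, against 0. The neural progenitor list was set apart in both.

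Requiring an overlap of 50% of the peak gave shares of 53.1% for replicate 1 and 33.6% for replicate 2, and 50% of both peaks 29.1% and 23.7%. The top 20000 peaks of each list gave 49.7% for replicate 1 and 44.5% for replicate 2. For replicate 2 the share was 17.9% with fold enrichment of at least 5 and 20.4% with −log10 q of at least 5, while for replicate 1, with the shorter lists, it was 60.8% and 71.2%. The rho of fold enrichment was 0.299 by nearest summit and 0.0668 with −log10 q of at least 5, where the range of values is narrower. The share of pooled peaks kept was 100% with fold enrichment of at least 5, 99.8% with −log10 q of at least 5, 54.0% by overlap with both replicate lists and 51.6% by overlap of 50% of either peak.

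Promoter enrichment was 3.29 in the pooled list, 2.81 with fold enrichment of at least 5, 2.93 with promoters of 2500 bp, 5.27 with protein-coding genes, 3.63 by summits and 3.11 to 3.201 with 1 replicate left out. Exon enrichment was 1.45 with −log10 q of at least 5, 1.06 with promoters of 2500 bp and 1.36 to 1.39 with 1 replicate left out. Intron enrichment was 1.36 in the pooled list, 1.61 and 1.47 under the fold and q limits, 1.18 with wider promoters, 1.51 with protein-coding genes, 1.31 by summits, 1.37 on autosomes and 1.3647 to 1.3649 with 1 replicate left out. The intergenic value was 0.479 in the pooled list, 0.308 and 0.371 under those limits, 0.433 with wider promoters, 0.502 with protein-coding genes, 0.493 by summits and 0.486 to 0.492 with 1 replicate left out. The downstream maximum over the TSS value at CpG-rich promoters was 6.83 in the pooled list, 43.9 and 15.6 under the limits and 6.62 to 7.19 with 1 replicate left out, and at CpG-poor ones 1.397 and 1.393 under the limits.

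Domains of at least 20 kb numbered 295 in the pooled list, 4 and 22 under the limits, 205 to 360 with 1 replicate left out, and 15 and 2985 at the shorter and longer joining distances. The longest spanned 30.2 and 40.8 kb under the limits, and 38.9 and 348 kb at those distances. The X over autosomes ratio was 0.0433 in the pooled list, 0 and 0.00843 under the limits, and 0.0400 to 0.0537 with 1 replicate left out. With the top 5000 distal peaks 2 motifs exceeded all permutations, and the E-box and HOX11 no longer did.

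Of 1215 alternatives for other values, 655 stayed within the same limits and 516 moved beyond them, mostly covered shares of named genes. A call was lost in 12, 6 for gene lists and 6 for motifs, and gained in 10, 3 and 7. Another 22 put a list that was not set apart on the other side of percentile 50. For the erythroid list this was 72.4 with windows of 100 kb, 60.2 without matching, 77.2 with density and CpG class and 74.6 with autosomal genes. For leukocytes it was 22.1 with −log10 q of at least 5 and 49.3 to 49.8 with 1 replicate left out. For adrenal and gonad it was 48.2 with gene bodies, and for sympathetic neurons 47.5 with length matching. For neurons it was 38.7 without matching, 37.5 with length matching and 43.7 with replicate 1 left out, where replicate 2 left out gave 81.4. For hepatocytes it was 64.1 with density and CpG class. For muscle it was 24.9 with 10 kb, 25.04 with gene bodies and 35.1 by number of peaks. For lung and gut it was 40.2 with 100 kb, 43.6 without matching, 46.7 with length matching and 49.1 by number of peaks. For the eye it was 27.9 with 10 kb, and for germ cells 74.1 with 100 kb.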

Other observations

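The gene families and Hox genes described here were chosen after the data had been examined. So were the tests of gene density, of milder reductions on the X chromosome, of weak enrichment, of CpG-rich promoters and of transcription factors of other lineages, while the tests of repeats, of halved enrichment and of GC content were set before their results were seen. Some signalling families were marked broadly. The 22 autosomal genes of the Notch pathway, which sets cell fates between neighbours, had a median covered share of 9.42% within 50 kb of the TSS, against 2.12% for random autosomal lists of the same size. The median was 8.98% in replicate 1 and 10.5% in replicate 2. The 8 Smad genes, which carry TGF-beta and BMP signals, had 10.4%, the 6 retinoid receptor genes 11.1% and the 4 Tcf/Lef genes of Wnt signalling 13.4%. The 19 Wnt ligand genes had 8.02% against 1.67%, and the 11 laminin genes of basement membranes 7.57% against 1.75%. Ligand families did not all behave alike, as the 20 Fgf genes had 2.67% against 1.98%, at percentile 77.1, and the 10 Bmp genes 1.77% against 1.72%, at percentile 52.4. At the other end, 8.25% of 1127 olfactory receptor genes and 4.27% of 328 vomeronasal receptor genes had any peak in the window. Of 100 cytochrome P450 genes, 39 had one, and the 53 keratin genes had a median of 1.26% against 3.21%. Genes of a family often sit side by side and share their windows, so these percentiles describe neighbourhoods more than independent genes.

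Along the Hox clusters, median marking within 2.5 kb of the TSS was higher in paralog groups 1 to 8 than in groups 9 to 13, which was not tested. It was 42.2% over 23 genes and 11.8% over 16 genes, 34.9% and 8.31% in replicate 1, and 41.0% and 14.1% in replicate 2. In HoxA the first group had a median of 52.9% and ranged from 32.0% to 86.9%. Hoxa10, at 37.8%, stood apart from Hoxa9 at 0 and Hoxa11 at 3.82%, and Hoxa13 was at 0 with 5.499% and 13.2% in the replicates. Among groups 9 to 13, Hoxd12 at 53.2% and Hoxb9 at 49.5% were above the median of the other group. In HoxD the medians were 30.1% and 18.2% in the replicated list, but 17.7% and 16.5% in replicate 1 and 29.7% and 30.4% in replicate 2, and Hoxd3 and Hoxd4 have nearly the same annotated start and so count 1 window 2 times. Hoxc5 was at 0, with its annotated start far upstream at position 102967443, beside Hoxc10, so values at single Hox genes depend on the annotated start.

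The scarcity of peaks on the X chromosome was weighed first, and a low gene density of that chromosome is argued against by its CpG-rich promoters, of which 15.04% had a peak within 5 kb against 88.1% on the autosomes. Repeats are argued against in the same way, as 15.9% of 107 CpG-rich X-linked promoters with repeat content at or under the autosomal median had a peak (95% Wilson interval 10.2 to 24.0%), against 89.8% of 4748 autosomal ones. A single active copy may lower enrichment and push peaks under the calling threshold, and when the fold enrichment of autosomal peaks was halved, a share of 0.142 of their base pairs stayed above the 5th percentile of all peaks. That is above the 0.0669 set as the upper limit for this cause, 2 times the observed ratio, and below the 0.2 set as the bound against it. Milder reductions to 0.667 and 0.75, which tissue of both sexes might give, left 0.474 and 0.668. Both exceed that bound. The calculation kept each remaining peak at its full width and cut on fold enrichment alone. The p-value threshold and the replication filter were left out, so it may overstate what remains and cannot decide on these reductions. As the profile of the X chromosome also had to be assumed from autosomal peaks, halved enrichment and milder reductions stay open. So does the authors' treatment of the control there, and no other biological explanation was tested.

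Peaks called in only 1 replicate were weighed next, 44421 in replicate 1 and 79066 in replicate 2. A GC bias between the libraries is argued against, as the median GC content of peaks only in replicate 2 minus that of peaks only in replicate 1 was -0.286 percentage points. Weak enrichment near the calling threshold stays open, and a rise of overlap with fold enrichment had been seen before its test. Among peaks of similar width, summits in the top quintile of fold enrichment lay in a peak of the other replicate more often than those in the lowest, on average by 21.9 percentage points for replicate 1 and 28.1 for replicate 2, and by 8.18 and 9.55 in the narrowest peaks. A difference in depth stays open too, because the lists hold no read counts, and so does one between the embryos pooled for each replicate.

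The position of the kidney gene lists above random lists was weighed last. CpG-rich promoters as the whole cause are argued against for the ureteric bud and stroma lists, of which the lower stayed at percentile 99.95 when random lists were matched on density and CpG class, and stay open for the podocyte list, at 96.63, and the tubule list, which lay on the threshold itself. That developmental transcription factors carry the mark whatever their lineage is argued against as the whole cause by 38 kidney factors with a median share of 6.51% (quartiles 2.53 to 12.7%), while 38 factors of other lineages had 1.97% (1.07 to 3.12%). Among 10000 random draws from both sets together, the kidney median was at percentile 100, also in each replicate alone. It was at 98.86 or above in windows of 10 and 100 kb and in gene bodies. These draws were not matched on gene density or CpG class, so a difference in either between the sets was not removed. The neural progenitor list, made of transcription factors of another lineage, was at percentile 90.05 in the main measure. It was past the threshold in 2 of 11 alternatives, windows of 10 kb and gene bodies, at up to 99.87. In those measures such marking was not confined to kidney lists. Some families not chosen by lineage were above random lists too. The 41 Fox factors had 3.94% against 1.81% and the 12 T-box factors 6.48% against 1.955%. Other families stayed short of the threshold, with 18 Sox factors at percentile 89.0 and 16 Krueppel-like factors at 95.9. The 385 zinc finger Zfp genes were at percentile 0.06, with 1.61% against 2.23%. The kidney factors and those of other lineages came from lists written for their lineage, and their values had been seen. A link of this marking to the kidney lineages therefore remains a hypothesis, which a second tissue could test and this series cannot.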
